A study of Homo sapiens with 18 samples.

How the data were processed

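Accessible chromatin was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in 18 libraries of PC9, an established human lung adenocarcinoma line that depends on mutant EGFR. Per the labels' protocols, cells were cryopreserved, thawed, lysed and tagmented. The libraries formed 6 groups of 3. PC9 was the unsorted vehicle (DMSO) population, and DTP (drug-tolerant persister) cells were the survivors of 8 days in 1 µM erlotinib, an EGFR kinase inhibitor. The other 4 groups were cells treated for 12 h with DMSO or 1 µM erlotinib and then sorted on Aldefluor, a fluorescent substrate of aldehyde dehydrogenase (ALDH), into ALDH-high and ALDH-low fractions. Groups were taken from the sample labels, which distinguish the libraries of a group by the letters a, b and c. The labels do not say whether these came from separate cultures, so the p-values measure the spread between libraries, which may be technical.

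Each library came with 1 deposited peak list, called separately per library. Per the submitters' processing notes, the processing used BWA, MACS 1.4.2 and the hg19 build. Read trimming, duplicate removal, shifting of reads for the transposase, calling parameters and any filter after calling are not given in the sources used here. Each peak carried a deposited score from the authors' peak caller, whose scale is not stated. The lowest score was 70 in each of the lists, so shorter and longer lists shared a floor. Scores were used only to rank or filter peaks within a list, and their medians are given as a description. Read depth is unknown, and a peak missing from a list means that it was not called there, which can reflect depth as well as closed chromatin. Peak numbers within the lists had gaps, which were counted as peaks removed after calling.

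Peaks on chromosomes 1 to 22 and X were merged across the 18 libraries wherever they shared at least 1 bp, giving 79483 union regions. Between 3 and 7 peaks per library lay elsewhere and were left out of the regions. A library held a region if at least 1 of its peaks fell in it. A region was called gained when all 3 libraries of the first group and none of the second held it, and lost in the reverse case. The 5 comparisons were: DTP against PC9, erlotinib against DMSO in each ALDH fraction, and ALDH-high against ALDH-low under each treatment. Numbers of peaks and covered bases were compared by exact two-sided permutation tests, whose smallest p for 3 against 3 libraries is 0.1. Tests over the 12 sorted libraries permuted the labels of treatment within fractions, or of fraction within treatments (400 assignments), with a smallest two-sided p of 0.005 and 0.0025 for a count in a single direction. In the same design each region was tested by an exact conditional permutation test with Benjamini-Hochberg adjustment. Similarity of libraries was the Jaccard index of called bases, the shared bases divided by the bases in either list. Its smallest p over the 12 sorted libraries is 0.01, since exchanging all labels within a fraction or a treatment leaves the difference unchanged. Overlaps between comparisons were tested by Fisher's exact test over regions that could have passed both. Shares in Giemsa-dark bands (the 2 darkest stain classes of hg19, which are AT-rich and gene-poor) were compared with regions held by all 6 libraries, by permuting 1 Mb bins 10000 times. Shares per chromosome were compared by permuting chromosome labels of bins 2000 times.

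Regions are given by hg19 position, counted from 1, and cytogenetic band. The rule for those that could be named was fixed before the data were examined: per comparison and direction, the 15 regions with the highest within-list score percentile in their weakest library. The same rule was applied to the regions that separated both fractions or both treatments. Gene coordinates and sequence of hg19 were not used here, and the gene table at hand was of another build, so no region was assigned to a gene. The share at promoters, the 16 gene lists and the motif search planned beforehand were therefore not run.

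Alternatives fixed beforehand were a score of at least 100, a region counted only where peaks covered at least 50% of it, lists of equal size (the 26225 highest-scoring peaks of each library, the length of the shortest list), all sequences, each library left out in turn, and a replicate block that exchanged only libraries with the same letter. Permuting whole bands and comparing with regions separated by other splits of the libraries were added after seeing the data, as were the tests of DTP regions in sorted libraries.

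The procedure was checked on the real lists and then on simulated data. In the real lists the union was the same as that from bedtools 2.31.1. The number of regions held was also the same in all 18 libraries, though which regions were held was not compared. With 200 changed regions among the 65904 of DTP against PC9, called at a rate of 0.95 in one group and 0.05 in the other, 70.5% were recovered, and 29.5% at rates of 0.8 and 0.2. The corresponding recovery for ALDH-high against ALDH-low under DMSO was 77.5% and 22.5% (200 of 45634 regions), so weak differences were mostly missed. Recovery depended only on the set rates, so its differences between comparisons reflect sampling. With no region changed, gained plus lost regions arising by chance numbered 744 for DTP against PC9, 601 and 582 for erlotinib in ALDH-low and ALDH-high cells, and 415 and 492 for the fractions under DMSO and erlotinib. The rates pooled the real libraries of both groups, so these numbers are a rough guide to chance. Other splits of the real libraries separated at most 355 regions for DTP and 707 for the fractions under erlotinib. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, with band positions from circlize 0.4.16.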

Results

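The 18 peak lists described open chromatin in untreated PC9 cells, in the persisters that survived 8 days of 1 µM erlotinib, and in ALDH-high and ALDH-low cells sorted after 12 h of DMSO or erlotinib. The design asks how the parental population, its drug-tolerant derivative and its ALDH fractions differ in chromatin structure. Of the 79483 regions called in any library, 14070 (17.7%) were held by all 18 libraries and 16858 (21.2%) by a single library. Unsorted PC9 had 40447 ± 1253 peaks and DTP 44110 ± 1658 (mean ± SD, n = 3 libraries per group throughout). Under DMSO, ALDH-low cells had 26348 ± 110 peaks and ALDH-high cells 31214 ± 1396. After 12 h of erlotinib the numbers were 36575 ± 4046 in ALDH-low and 38548 ± 3659 in ALDH-high cells. Peaks covered between 29.0 ± 0.365 Mb (ALDH-low, DMSO) and 43.1 ± 3.95 Mb (ALDH-high, erlotinib). Median peak width was 833 ± 16.5 bp in PC9 and 856 ± 25.1 bp in DTP, and between 983 and 1005 bp in the means of the sorted groups. The depth behind these lists is unknown.

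**Figure D1:**
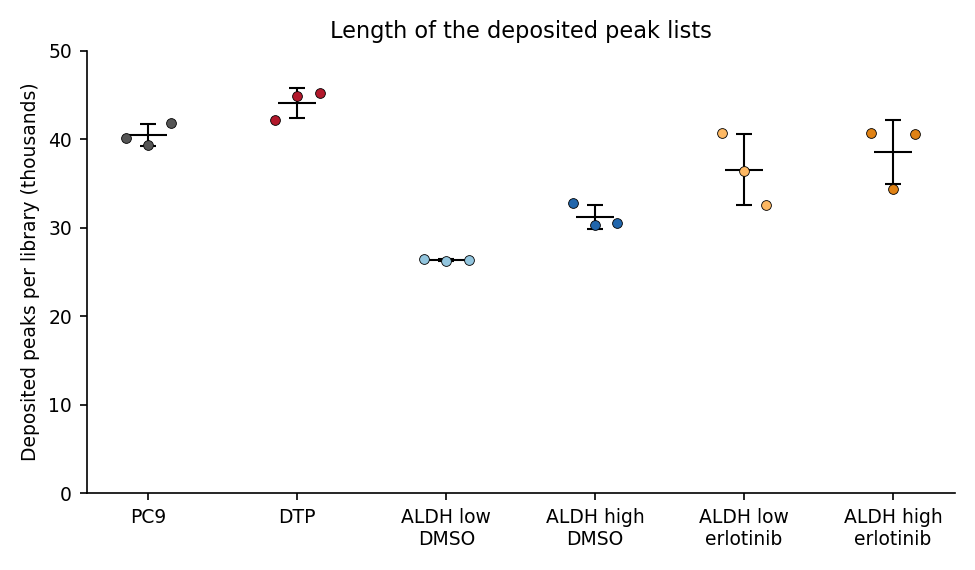
Deposited peaks per library (y axis, in units of 1000) in the 6 groups (x axis). Points are libraries, and horizontal marks with bars are the mean and SD of 3 libraries; ALDH-low DMSO lists were the shortest, at 26228 to 26444 peaks.

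Persister cells differed from parental PC9 in both directions. In DTP, 4446 regions were gained, present in all 3 DTP libraries and absent from all 3 PC9 libraries, and 2425 were lost, against 24186 held by all 6. Among the gained regions ranking highest by score was 1p33 (chromosome 1, 47269424 to 47271375), which all 6 libraries of sorted cells treated with erlotinib for 12 h also held and no sorted DMSO library did. The regions at 6q21 (chromosome 6, 114465665 to 114467222), 11q14.2 (chromosome 11, 86710673 to 86711928), 2q31.2 (chromosome 2, 180575238 to 180576937) and 17p11.2 (chromosome 17, 18849448 to 18850581) behaved alike, making 5 of the 15 named. Regions at 2p14 (chromosome 2, 67066582 to 67067921) and 10q21.2 (chromosome 10, 64343517 to 64344912) were called in no library other than the 3 of DTP. Of the 15 named lost regions, 6 were held by all 12 sorted libraries, with or without erlotinib. They included 3q27.1 (chromosome 3, 183642242 to 183643742), 4q33 (chromosome 4, 170266112 to 170267328), 3p22.1 (chromosome 3, 43673424 to 43674467) and 2q35 (chromosome 2, 217930171 to 217931649). The lost region at 6p24.3 (chromosome 6, 7644371 to 7645466) was held by PC9 and all 6 sorted DMSO libraries and by no erlotinib library of either kind.

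DTP lists were 9.06% longer than PC9 lists (3663 more peaks on chromosomes 1 to 22 and X, exact permutation p = 0.1, the smallest possible) and covered 4.87 Mb more. Libraries within these groups shared more bases than libraries between them, with a mean Jaccard index of 0.640 within and 0.525 between (difference 0.116, exact permutation p = 0.1). Gains made up 64.7% of the separated regions in the lists as deposited and 52.1% in lists of equal size, where 2222 regions were gained and 2046 lost.

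The regions gained in DTP lay in Giemsa-dark bands more often than the regions common to both groups, but less often than the genome. The dark share was 25.1% of 4446 gained regions, 21.7% of 2425 lost regions and 18.2% of the regions common to all 6 libraries. Dark bands make up 29.8% of chromosomes 1 to 22 and X, and held 26.6% of the regions called in a single library. Common regions were wider (median 1489 bp) than gained (979 bp) and lost regions (956 bp), and neither width nor score was matched. Gained and lost regions both exceeded the common regions (permutation of bins, p = 0.0001 for gains, the smallest possible, and p = 0.0015 for losses; adjusted over 10 tests, 0.001 and 0.00375). Against regions separated by other splits of the same libraries, the losses were 0.847 points higher (permutation p = 0.563), so their call ended there. Gained and lost regions also differed from each other (permutation p = 0.0047). Gained regions were over-represented on chromosome 13 (169 regions, 1.52 times the common share, adjusted p = 0.0288 over 230 tests by permutation). They were under-represented on chromosome 22 (37 regions, 0.470 times, adjusted permutation p = 0.0128), where the unadjusted permutation p was 0.039 with lists of equal size (−0.592 points, against −0.937) and 0.0495 at a score of at least 100. Lost regions were under-represented on chromosome 19 (32 regions, 0.366 times, adjusted permutation p = 0.0128). Lost regions were over-represented on chromosome 6 (209 regions, 1.38 times, adjusted permutation p = 0.0128) and under-represented on chromosome 16 (47 regions, 0.568 times, adjusted permutation p = 0.0128). Gains were also fewer on chromosomes 17 and 19 and losses more frequent on chromosome 2, but these calls ended with lists of equal size (permutation p = 0.198, 0.153 and 0.246). In the other comparisons the tests that passed adjustment were all on chromosome 19, where losses at 12 h were 0.271 times the common share in ALDH-low and 0.339 times in ALDH-high cells and gains 0.707 times in ALDH-high cells. There, losses in ALDH-high against ALDH-low cells under DMSO were 3.04 times the common share (7 regions), and gains under erlotinib 0.297 times (6 regions). Chromosome shares were compared with common regions only, not with regions separated by other splits. Whether they differ from those of any variable regions was therefore not tested.

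**Figure D2:**
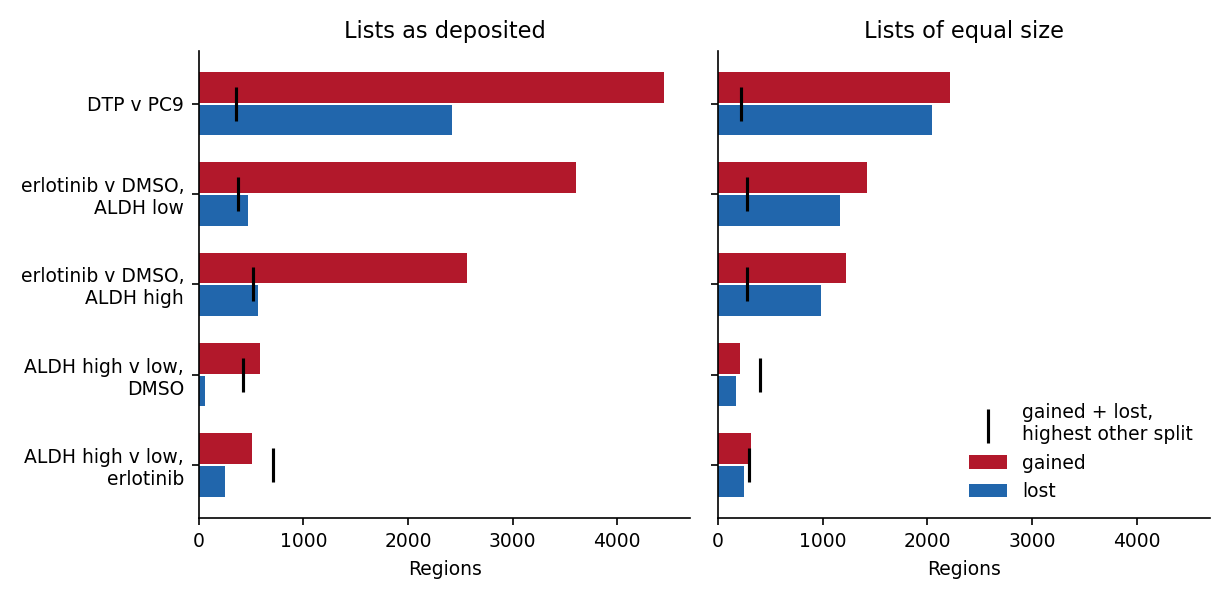
Regions gained and lost (x axis, number of regions) in the 5 comparisons (y axis), with the lists as deposited on the left and cut to equal size on the right. Black marks give gained plus lost regions in the highest of the other splits of the same 6 libraries, 355 for DTP against PC9 with lists as deposited.

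The regions called after 12 h of erlotinib differed from those under DMSO in both ALDH fractions. Median deposited scores were higher after erlotinib too. They were 170 ± 6.59 against 142 ± 0.450 in ALDH-low and 168 ± 6.64 against 150 ± 2.87 in ALDH-high libraries. DTP and PC9 had 136 and 140. Whether read depth differed with treatment could not be tested. In ALDH-low cells 3607 regions were gained and 469 lost, and in ALDH-high cells 2567 were gained and 567 lost. Cells were sorted after treatment, so a fraction need not hold the same cells under erlotinib as under DMSO. This was not tested. Regions present in all 6 erlotinib libraries and in none of the 6 DMSO libraries numbered 1000, and 103 showed the reverse. The highest-ranking of the 1000 was at 3q29 (chromosome 3, 194232900 to 194234505), followed by 14q32.31 (chromosome 14, 102562621 to 102564892) and 15q26.1 (chromosome 15, 90310097 to 90311770). The region at 3q29 was also in all DTP libraries and in no PC9 library, as were 8 of the 15 named, among them 3q11.2 (chromosome 3, 97776316 to 97777974) and 1p21.2 (chromosome 1, 101723022 to 101724318). That at 15q26.1 was called in neither PC9 nor DTP. The highest-ranking regions lost in both fractions were at 7q36.1 (chromosome 7, 148930144 to 148931792) and 5q23.3 (chromosome 5, 127563203 to 127564512). Of these, 5q23.3 was held by all 3 DTP libraries and 7q36.1 by 2 of them.

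Exact permutation within fractions gave p = 0.0025 for the 1000 regions and p = 0.005 for the 103, the latter being the smallest possible because the exchanged labels give a larger count. The other 398 assignments of the labels separated 4.10 regions on average. Single regions did not pass adjustment: of 13213 testable regions, 2775 were higher and 360 lower at an unadjusted exact permutation p under 0.05, and none at an adjusted p under 0.05 (smallest adjusted p = 0.0599). A region's p cannot go below 0.005, so none could pass unless still more regions were fully separated. Both fractions shared more of their gains than independent lists would (expected 112, odds ratio 34.5) and of their losses (expected 2.87, odds ratio 188, Fisher's exact p = 4.49e-148). These expected numbers treat all regions as equally likely to be called, which can inflate the odds ratios. Both fractions of a treatment may also have been sorted from the same treated culture, which the labels do not settle. Agreement between fractions, and the tests over both, thus need not replicate the treatment.

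Erlotinib lists were 38.8% longer than DMSO lists in ALDH-low cells and 23.5% longer in ALDH-high cells (exact permutation p = 0.1 each). Over both fractions the difference was 8780 peaks (exact permutation p = 0.005), and it did not differ detectably between fractions (2895 peaks, exact permutation p = 0.485). The second test exchanged fraction labels within treatments, so its p is against no difference between fractions under either treatment. Within-group similarity exceeded that between treatments by 0.0875 (exact permutation p = 0.01). With lists of equal size the numbers gained and lost became 1425 and 1162 in ALDH-low cells and 1220 and 983 in ALDH-high cells, so that gains fell from 88.5% to 55.1% and from 81.9% to 55.4% of the separated regions. In both fractions together 447 regions were then gained and 329 lost. Leaving out ALDH-low erlotinib library c raised the gains in ALDH-low cells to 5995, and leaving out ALDH-high erlotinib library b raised those in ALDH-high cells to 4615. Lost regions lay in dark bands more often than common regions in ALDH-high cells (25.7% against 17.4%, permutation p = 0.0004, adjusted 0.002). Against regions separated by other splits the difference was 5.45 points (permutation p = 0.0137, adjusted 0.0685), which did not pass adjustment. In ALDH-low cells the lost regions were 6.08 points above the common share of 16.9% (permutation p = 0.0493, adjusted 0.0704), and the gained regions had 18.4% (permutation p = 0.14). Gained regions of ALDH-high cells had 20.1% (permutation p = 0.0066, adjusted 0.0132). That call ended at a score of at least 100 (permutation p = 0.11) and with 50% coverage (p = 0.0662), and against regions separated by other splits the direction turned (−0.237 points, p = 0.766).

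**Figure D3:**
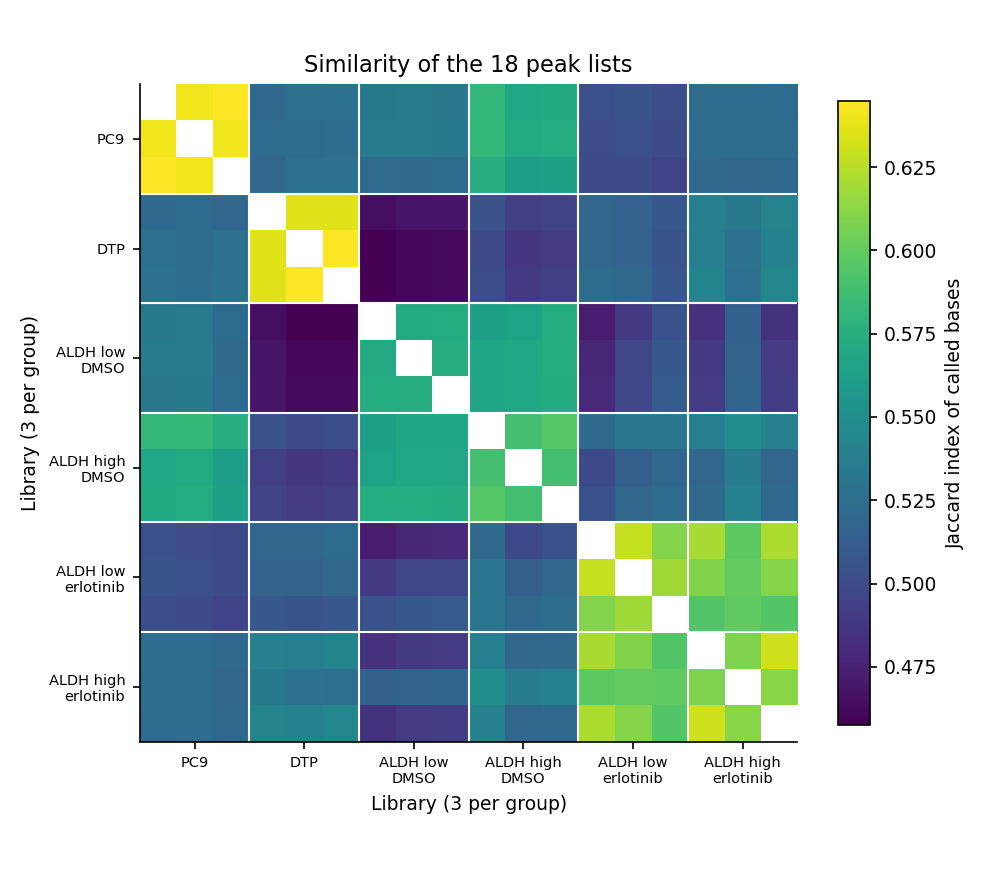
Jaccard index of called bases (colour) for each pair of the 18 libraries, ordered by group on both axes, with the diagonal left blank. Pairs within PC9 and within DTP averaged 0.642 and 0.639, and pairs between ALDH-low and ALDH-high erlotinib libraries 0.605.

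ALDH-high and ALDH-low cells differed little. Under DMSO, 582 regions were gained in ALDH-high cells and 64 lost, and under erlotinib 512 were gained and 256 lost. Unchanged regions simulated at the same calling rates gave 415 and 492 separated regions, against these 646 and 768. The highest other split of the real libraries gave 425 and 707. Regions held by all 6 ALDH-high libraries and none of the 6 ALDH-low libraries numbered 12, and none showed the reverse. They included 6p22.3 (chromosome 6, 21679005 to 21680589), 7p14.1 (chromosome 7, 41955673 to 41956896) and 2p22.1 (chromosome 2, 39798073 to 39799326), all of which were also held by every PC9 and DTP library. In the weakest library that held it, each of the 12 had a low within-list score percentile, between 0.997 (1p12) and 13.4 (6p22.3). These values lie near the calling floor. The 15 named regions gained with erlotinib in both fractions had 68.6 to 92.9. Of the 12, 10 were held by all PC9 libraries. The region at 7p15.2 (chromosome 7, 27481805 to 27482831) was in all PC9 libraries and no DTP library. Under DMSO, the highest-ranking gain was at 1p22.2 (chromosome 1, 89487111 to 89489195) and the highest-ranking loss at 2q33.2 (chromosome 2, 204192408 to 204193698). Both were held by all 6 erlotinib libraries of either fraction.

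The count of 12 was beyond that of all other assignments (highest other 8, exact permutation p = 0.005 for both directions together). With lists of equal size 1 region was higher and 2 were lower (exact permutation p = 0.335), so the count did not hold once list length was matched. No single region passed adjustment in the exact permutation test (smallest adjusted p = 0.889; 100 regions higher and 8 lower at an unadjusted p under 0.05). A region's p cannot go below 0.005, so among 6377 testable regions none could pass unless many were fully separated. The result therefore says little about single regions. ALDH-high lists held 3420 more peaks than ALDH-low lists over both treatments (exact permutation p = 0.06). This became an exact permutation p of 0.015 without ALDH-low erlotinib library a (4444 peaks) or without ALDH-high erlotinib library b (4476 peaks). Under DMSO the difference was 4867 peaks (exact permutation p = 0.1) and under erlotinib 1972 (p = 0.6), which turned to −21.7 without ALDH-low erlotinib library c. Similarity within fractions exceeded that between them by 0.0128 (exact permutation p = 0.01), and by 0.0109 with lists of equal size (p = 0.01). In equal-size lists, however, ALDH-low DMSO libraries shared less with each other (0.574) than with ALDH-high DMSO libraries (0.581). ALDH-high DMSO libraries shared 0.600 with each other, and the difference under DMSO was 0.00523. Gains were 90.1% of the separated regions under DMSO and 66.7% under erlotinib, and 54.7% and 56.0% with lists of equal size (210 and 174 regions, and 316 and 248). Dark-band shares of ALDH-high gains were 22.7% under DMSO (common regions 17.7%, permutation p = 0.0282, adjusted 0.047) and 24.6% under erlotinib (common 16.7%, p = 0.0007, adjusted 0.00233). Neither held with lists of equal size (permutation p = 0.657 and 0.0945). The corresponding losses had 18.8% (permutation p = 0.897) and 18.4% (permutation p = 0.635).

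The 8-day and 12 h responses to erlotinib shared regions. Of 1657 regions gained at 12 h in ALDH-low cells that could have been gained in DTP too, 607 were (expected 256, odds ratio 3.54, Fisher's exact p = 6.0e-107). In ALDH-high cells 593 of 1399 were shared (expected 216, odds ratio 4.57, Fisher's exact p = 4.04e-138). Shared losses numbered 70 in ALDH-low cells (expected 6.05, odds ratio 18.6, Fisher's exact p = 6.47e-55) and 148 in ALDH-high cells (expected 11.1, odds ratio 26.9, Fisher's exact p = 7.19e-129). Regions that moved in opposite directions, lost in DTP and gained at 12 h, numbered 40 in ALDH-low and 28 in ALDH-high cells, and those gained in DTP and lost at 12 h numbered 0 and 1. The comparisons shared no library. Neighbouring regions are not independent, so these p-values are too small to the extent that regions move together. The expected numbers also treat all regions as equally likely to be called, though 16858 of the 79483 were called in a single library. Part of the excess can come from that, so the odds ratios do not measure a shared response alone. With lists of equal size the shared regions were 253, 285, 283 and 298, in the order low gained, high gained, low lost and high lost. Of the 1000 regions gained at 12 h in both fractions, 320 were gained in DTP, 530 were held by all DTP libraries and 66 by all PC9 libraries. Of the 103 lost in both, 26 were lost in DTP and 40 were held by all DTP libraries.

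The share of DTP-gained regions called in sorted cells was higher after erlotinib, and that of DTP-lost regions lower, in both fractions. With lists of equal size, DTP-gained regions were called in 13.1% ± 0.388 of cases in ALDH-low DMSO libraries and 35.3% ± 0.865 after erlotinib, and in 13.3% ± 0.749 and 37.8% ± 0.659 in ALDH-high libraries (SD, n = 3). DTP-lost regions fell from 61.7% ± 1.61 to 28.0% ± 0.833 in ALDH-low and from 65.9% ± 0.764 to 31.5% ± 1.01 in ALDH-high libraries. Both shifts had an exact permutation p of 0.005 within fractions (adjusted over 18 tests, 0.0129). As deposited, the erlotinib effect was 27.5 percentage points on DTP-gained and −11.8 on DTP-lost regions (exact permutation p = 0.005 each). ALDH-high libraries held 3.84 points more of the DTP-lost regions than ALDH-low libraries (exact permutation p = 0.005, adjusted 0.0129) and 1.37 points more of the DTP-gained regions (p = 0.035, adjusted 0.063). As deposited these were 9.27 points (exact permutation p = 0.01, adjusted 0.0225) and 3.64 points (p = 0.105), the latter 5.17 points with p = 0.035 without ALDH-high erlotinib library b.

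**Figure D4:**
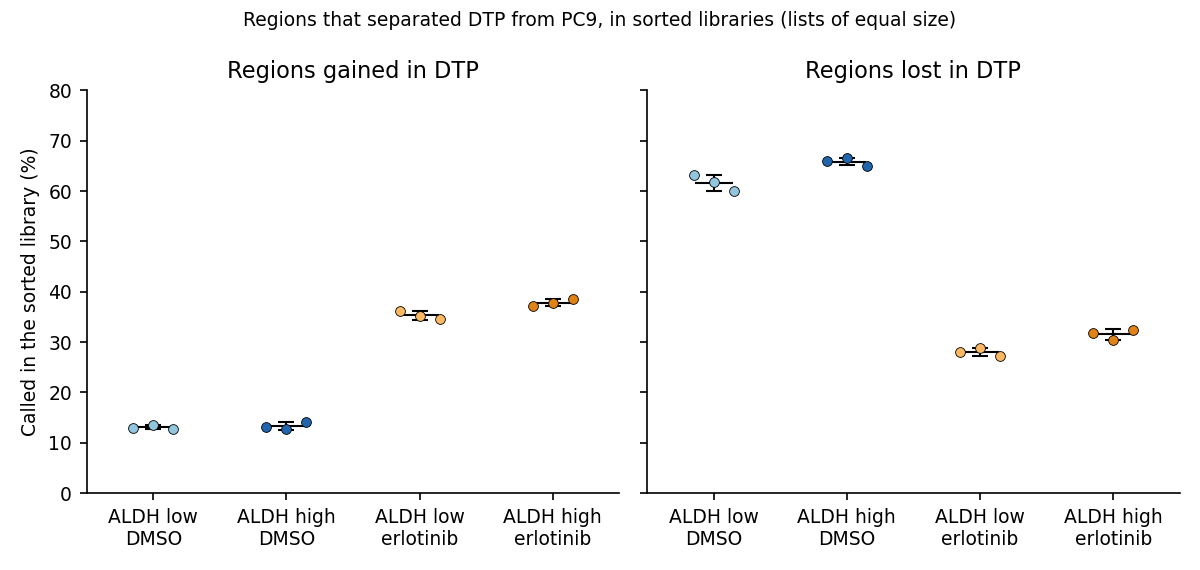
Share of the regions gained (left) and lost (right) in DTP against PC9 that were called in each sorted library (%, y axis), with lists of equal size. Points are libraries, and marks with bars the mean and SD of 3; DTP-gained regions averaged 13.1% and 13.3% under DMSO and 35.3% and 37.8% after erlotinib.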

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

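All tests in this part were chosen after the result was seen. Peaks removed after calling, which no comparison of peaks uses, set the sorted libraries apart: they lacked 322 numbered peaks on average (0.982% of those called), against 112 (0.265%) in the unsorted libraries. The fewest in a sorted library exceeded the most in an unsorted one by 183, and median peak width separated the same libraries. For differences of treatment or ALDH fraction, the largest difference between sorted groups was 0.0987 times the sorted-unsorted difference for the number removed, 0.145 times for width, and 0.482 times for the percent removed. With any 1 library left out the first and the second stayed at or under 0.114 and 0.178, which argues against such differences as the cause for the number removed and for width. The percent, which shrinks as lists lengthen, reached 0.533, past the bound of 0.5, so their part in its size stays open. Even so, the lowest percent in a sorted library (0.775%) exceeded the highest in an unsorted one (0.296%). Sorted libraries of each treatment and fraction thus lay above all unsorted ones, which argues against these as the whole cause for the percent. A library or sequencing batch, a different filter for the sorted lists, the sorting procedure and anything else common to the sorted groups coincide with this split and cannot be told apart.

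With lists as deposited, the DTP index, the share of DTP-gained minus that of DTP-lost regions called in a library, rose less with erlotinib in ALDH-low than in ALDH-high cells, with a difference (low minus high) of −11.75 percentage points (exact permutation p = 0.045, adjusted over 18 tests 0.0736). It was −2.89 points with lists of equal size (exact permutation p = 0.23). Both tests exchanged fraction labels within treatments. Their p-values are thus against no difference between fractions under either treatment, not against equal drug effects alone.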

How the results depend on the processing

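The tests against other splits of the libraries, the bounds that judge list length from lists of equal size, the band alternatives named below as added, the alternatives for single chromosomes and windows and the tests of DTP regions in sorted libraries were chosen after the results were seen. Lists of equal size and the other alternatives were fixed before the data were examined. Of 730 recomputed values, 617 kept their direction and side of the threshold or moved by less than 1.5 times, 73 moved by more, 20 no longer passed the threshold, 6 newly passed it and 14 reversed. For tests of 3 against 3 libraries only the direction was judged, and for counts only their size, without a p-value. The replicate block and the permuted whole bands keep the value and can change only p. All sequences add between 3 and 7 peaks per library. Many of the 617 could therefore hardly change, so their share does not measure robustness. Promoter share, gene lists and motifs were not run. Depth is unknown, and lists that share a score floor but differ in length limit every comparison of presence. The cause was not tested except where stated.

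Other splits of the same 6 libraries number 9, too few for a share under 0.05: in each comparison of the lists as deposited 1 of the 10 splits, the real one, reached the real count. The real and highest other counts were 6871 and 355 for DTP, 4076 and 372 for erlotinib in ALDH-low, 3134 and 522 in ALDH-high, and 646 and 425 (DMSO) and 768 and 707 (erlotinib) for the fractions. Among 100 splits within strata only the real one reached 1103 regions for erlotinib (highest other 56) and 12 for the fractions (highest other 7, and 8 over all 400 assignments). As deposited, both counts were thus beyond other groupings of these libraries at 0.05. The libraries of a group, and both fractions of a treatment, may share a culture, so chance differences between cultures or sorts were not covered. With lists of equal size 4 of the 10 splits separated at least the 384 regions of the fractions under DMSO (highest other 401), and at a score of at least 100, 2 of the 10 separated at least the 575 regions of the fractions under erlotinib (highest other 637).

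Gains at 12 h in lists of equal size were on average 55.2% of the separated regions. Equal sizes push gains and losses towards balance by construction, and all 5 comparisons came to between 52.1% and 56.0%, so longer lists and a net opening of chromatin cannot be told apart as the source of the excess. The separation itself remained beyond that of other splits, with 776 regions in both fractions against 24 in the highest other. For the fractions 3 regions were left, against 8. In equal-size lists gained regions were 2222 for DTP, 1425 and 1220 for erlotinib in ALDH-low and ALDH-high, and 210 and 316 for the fractions under DMSO and erlotinib. Lost regions were 1162, 983 and 174 for erlotinib in ALDH-low, in ALDH-high and for the fractions under DMSO. Over both strata erlotinib gave 447 higher and 329 lower, and the fractions 1 and 2. Overlaps of DTP with 12 h were 253 and 285 gained and 283 and 298 lost (ALDH-low, ALDH-high). The difference in covered bases between fractions under erlotinib turned to −0.132 Mb, and DTP-gained regions differed between fractions by 1.37 points (exact permutation p = 0.035).

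Dark-band differences from common regions, in percentage points, changed as follows. With equal-size lists ALDH-high gains fell to 2.11 (DMSO) and 4.17 (erlotinib) and losses under erlotinib to −0.591. At a score of at least 100, gains at 12 h were −1.39 in ALDH-low and 1.72 in ALDH-high (permutation p = 0.11, call lost), and ALDH-high gains under DMSO 1.69 (p = 0.347, call lost). With 50% coverage, 12 h losses in ALDH-low were 5.67, 12 h gains in ALDH-high 1.59 (permutation p = 0.0662), ALDH-high gains under DMSO 4.20 (p = 0.0873), and losses between fractions −7.32 (DMSO) and −1.40 (erlotinib). All sequences gave 6.08 for 12 h losses in ALDH-low (permutation p = 0.0518). Against regions of the other splits, added after seeing the data, DTP losses were 0.847 (permutation p = 0.563); 12 h gains −1.23 and −0.237 in ALDH-low and ALDH-high; 12 h losses 3.39 in ALDH-low and 5.45 in ALDH-high (permutation p = 0.0137, adjusted 0.0685); and for the fractions gains 3.82 and losses −0.106 under DMSO, and gains 3.48 and losses −2.77 under erlotinib. The count lower in ALDH-high over both treatments was 1 at a score of at least 100 and 1 with 50% coverage.

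Leaving out a library loosens the criterion, so counts rise by construction. Gained and lost regions ranged from 4239 to 5995 and 554 to 814 (erlotinib, ALDH-low), 3252 to 4615 and 696 to 1017 (ALDH-high), 1094 to 1368 and 131 to 244 (fractions, DMSO), and 697 to 1498 and 388 to 869 (fractions, erlotinib). Over both treatments the fractions gave 12 to 27 higher and 0 to 2 lower. Shared losses were 70 to 141 in ALDH-low and 152 to 243 in ALDH-high. Peaks over both treatments differed between fractions by 2423 to 4476, and under erlotinib by −21.7 to 4085, with covered bases from −0.591 to 3.83 Mb, both turning without ALDH-low erlotinib library c. DTP-gained regions differed by 2.35 to 5.17 points between fractions. Dark-band differences ranged from 0.688 to 2.15 (12 h gains, ALDH-low, past the threshold without ALDH-low erlotinib library c). For the fractions they ranged from 1.57 to 5.12 (DMSO gains), −3.34 to 2.50 (DMSO losses) and 0.249 to 3.57 (erlotinib losses).

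The letters did not pair the libraries: deviations of same-letter libraries correlated between −0.0148 and 0.0173. With the replicate block, the 8 sign flips of a single comparison cannot go below an exact permutation p of 0.25, which 3663 peaks for DTP reached. Over 64 assignments the 1000 regions gained with erlotinib had an exact permutation p of 0.0156, the 103 lost 0.0313, the 8780 peaks 0.0313 and the difference of 3420 peaks between fractions 0.0938. No call changed.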

Other observations

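The dark share of DTP gains against common regions, as deposited and with lists of equal size, was planned before the data were examined; the other tests in this part were chosen afterwards, as was the use of the equal-size value to judge list length. For the DTP index and the dark share against other splits, the bounds were written before that test had been run, but after the overlap of the 12 h and DTP regions and the dark shares against common regions had been seen. Vehicle-treated ALDH-high libraries resembled unsorted PC9 more than vehicle-treated ALDH-low libraries did, with mean Jaccard indices of 0.573 (0.563 to 0.583) and 0.530 (0.522 to 0.535), and of 0.586 and 0.565 with lists of equal size. The ALDH-low DMSO libraries were also less alike among themselves (0.574 with lists of equal size) than the ALDH-high DMSO libraries (0.600). DTP libraries stood closer to the 12 h erlotinib libraries (0.515 for ALDH-low and 0.537 for ALDH-high) than to the DMSO libraries (0.462 and 0.495). Equal-size lists gave 0.518 and 0.539 against 0.497 and 0.511. DTP and PC9 libraries had a mean index of 0.525 (0.527 with lists of equal size), above that of DTP and ALDH-low erlotinib libraries. These differences were not tested. In the windows of 1 Mb, losses in DTP gave the smallest p at 2q35 (chromosome 2, 217000001 to 218000000), with 10 of the 37 called regions lost, the only window of that comparison to pass adjustment (one-sided Fisher's exact test, adjusted p = 0.00177). The window also held 4 gained regions, and its lost regions were 4 with lists of equal size and 4 at a score of at least 100. For gains the smallest p was at 13q31.1 (chromosome 13, 80000001 to 81000000), with 10 of 31 (Fisher's exact test, adjusted p = 0.065). This window held 1 lost region, and its gained regions were 4 with lists of equal size and 8 at a score of at least 100.

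A first hypothesis was that ALDH-high cells already resemble persisters. With lists of equal size the DTP index was lower in ALDH-high libraries, with a difference from ALDH-low of −2.47 percentage points (−3.92 under DMSO and −1.03 under erlotinib; exact permutation p = 0.015, adjusted 0.03), not the rise it predicts, although DTP-gained regions alone were 1.37 points higher. As deposited the difference was −5.64 points (exact permutation p = 0.06, adjusted 0.09), made of −11.5 under DMSO and 0.24 under erlotinib, so a lower index in ALDH-high libraries did not hold in those lists. The Jaccard index went the other way: with lists of equal size ALDH-high libraries shared more with DTP than ALDH-low libraries did. The means were 0.511 against 0.497 under DMSO and 0.539 against 0.518 under erlotinib. They also shared more with PC9 (0.586 against 0.565, and 0.521 against 0.497). These means were not tested, so the hypothesis is not settled. A second was that 12 h of erlotinib opens and closes the regions that differ between DTP and PC9. The index rose by 57.4 points, and by 39.3 as deposited (exact permutation p = 0.005 each), as that hypothesis predicts, which is consistent with an early component of the persister pattern but does not show that the same cells persist.

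Regions gained in DTP lay in Giemsa-dark bands more often than the regions common to DTP and PC9 (25.1% against 18.2%), though less often than the genome as a whole (29.8%) or regions called in a single library (26.6%). A general tendency of variable regions to lie there was argued against as the whole cause, since gains exceeded regions separated by other splits of the same libraries by 4.30 points (permutation p = 0.0005). List length stays open. With lists of equal size gains exceeded common regions by 5.19 points (permutation p = 0.0001, the smallest possible). DTP losses exceeded them too, by 2.85 points, so that excess is not particular to gains. With lists of equal size, gains were not compared with regions separated by other splits. A change in chromatin of AT-rich, gene-poor bands may contribute, as a hypothesis. Region width, peak score, base composition, repeat content, copy number and depth were not tested here and stay open.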
